A study of Homo sapiens with 8 samples.

How the data were processed

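Human K562 and Jurkat cells, both expressing the CRISPR interference repressor dCas9-KRAB, received a pooled lentiviral library in which each construct carried 2 sgRNAs and barcodes that mark the pair. K562 is a chronic myeloid leukemia line that carries the BCR-ABL fusion, and Jurkat is a T-cell leukemia line. Per the labels, infected cells were selected with puromycin, and genomic DNA was taken at T0 (day 5 after infection for K562 and day 6 for Jurkat) and again at the endpoint, 10 days after T0. The sgRNA and barcode regions were amplified by PCR and sequenced on an Illumina instrument. The 8 libraries fall into 4 groups of 2 replicates: K562 T0, K562 Endpoint, Jurkat T0 and Jurkat Endpoint. Nothing in the labels says that the replicates came from separate infections or cultures, so p-values measure only the spread between these samples, which may be technical.

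The authors deposited whole-number read counts for 1044484 constructs, that is, for every ordered pair of 1022 sgRNAs. Per the file headers, the counts come from 3 readouts, named barcode, sgRNA and tripleseq, in 20 columns, all of which were matched to samples. K562 T0 has only the barcode readout, so the barcode readout was used for all 8 libraries, and the other readouts served as alternatives. In those alternatives K562 T0 still came from the barcode readout. For K562 they therefore set an endpoint of 1 readout against a T0 of another. Demultiplexing used bcl2fastq 2.17.1.14 and the build is hg19, per the submitters' processing notes; the counting program is not given in the sources used here. In 44747 constructs (4.28%) all Jurkat cells were blank, and no construct had a 0 in every Jurkat column, so blanks were taken as 0. The authors also deposited phenotypes on a log2 scale for each construct and replicate. Tested against the counts, these equal log2 of endpoint over T0 with 10 added to each count, minus the median of constructs with 2 non-targeting sgRNAs, divided by a constant per replicate. In the authors' deposited table these constants are 6.91 and 7.61 for K562 and 6.15 and 6.44 for Jurkat replicates 1 and 2. The deposited sequence list gave 1022 distinct sgRNA sequences.

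The library holds 18 non-targeting sgRNAs and 1004 sgRNAs against 472 genes, of which 53 have 1 sgRNA, 306 have 2 and 113 have 3. The barcode readout held 430138312 to 634558090 reads per library, with a median of 202 to 447 reads per construct. The reads carry no molecular identifiers, so PCR copies of 1 molecule were counted as separate reads. Standard errors of growth effects and scores come from the fits and include the spread between replicate libraries. The 324 constructs with 2 non-targeting sgRNAs, which set the scale of the growth effects, held 88091 to 872462 reads per library.

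For growth effects of single genes, counts were summed per gene over all constructs that pair a gene's sgRNA with a non-targeting sgRNA, in both positions. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in 1 fit of all 8 libraries with 4 group means and 4 residual degrees of freedom, with the reads of the non-targeting constructs as library size. This scale was chosen because most genes of the library were picked for a growth effect, while TMM assumes that most do not change. Growth effects are log2 of endpoint over T0, with standard errors (SE). The contrasts were K562, Jurkat, and Jurkat minus K562, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Of 472 genes, 471 had enough reads to be tested. Growth effects were not divided by doublings.

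For genetic interactions, sgRNAs with a median T0 count under 35 at either position in any T0 library were left out. This removed 52 sgRNAs and 3 genes and left 970 sgRNAs, 16 of them non-targeting, and 469 genes. Each construct's log2 effect was computed per replicate with a pseudocount of 10 and centred on the non-targeting constructs, each endpoint being set against the T0 of the same replicate number. The 2 orders of a pair were averaged. For each query sgRNA, a quadratic curve was fitted to its pair values over the partners' single effects, and the residual from the curve was the score. Scores were averaged over both queries and over the sgRNA pairs of 2 genes, giving 109746 gene pairs. A score below 0 means that the pair was depleted more than its expectation, and a score above 0 that it was depleted less. The 4 replicate maps were tested with limma 3.58.1, with a trend on the mean log2 count, in 1 fit with 2 line means and 2 residual degrees of freedom, so that both lines shared 1 estimate of the spread. The fit of each line alone was added after the data were seen.

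Gene lists for complexes and pathways were tested with camera at a preset correlation of 0.01 for growth effects. For interactions, the mean score within a list or between lists, and the mean correlation of profiles within a list, were set against 10000 permutations of the gene labels. Tests for the difference of list scores between the lines were added after the data were seen. Adjusted p-values of lists are Benjamini-Hochberg values over lists and contrasts or lines. The lists cover the cytosolic ribosome, mitochondrial ribosome and translation, proteasome, respiratory complex I, respiratory complexes III and IV and ATP synthase, mevalonate and cholesterol synthesis, DNA damage checkpoint and repair, DNA replication, cytosolic aminoacyl-tRNA synthetases, splicing, translation initiation and elongation, ribosome biogenesis, Mediator and RNA polymerase II, chromatin, ER-Golgi trafficking, ER protein entry, heme and iron-sulfur clusters, chaperonin and folding, mitochondrial import, nucleotide synthesis, V-ATPase, mTORC1 and growth control, mitosis and cell cycle, RNA decay and export, erythroid and BCR-ABL signalling, and T-lineage and Notch signalling. The measured genes of mTORC1 and growth control were MAPKAP1, MAX, MTOR, RPTOR, SEH1L and TTI2. This list is broader than mTORC1, and mTORC1 stands for the whole list where the name is shortened. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 did the remaining computing and drawing.

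The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be later. The rule names, per line, the 10 lowest and 5 highest growth effects past the threshold and the 8 lowest and 8 highest interaction scores past it with the same sign in both replicates. It also names the 8 largest growth differences between the lines in each direction, the 10 strongest pairs past the threshold in both lines, the 6 largest interaction differences in each direction, and up to 4 members or pairs of each described list. FDPS and HUS1 are named whatever their value, since the study is known for that link.

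The alternatives for growth were TMM scaling, DESeq2 1.42.0 with its own or with non-targeting size factors, a T0 minimum, a replicate block, every sgRNA of a gene passing alone, Jurkat effects scaled to K562, and each library left out. For interactions they were pseudocounts of 1 and 30, no T0 minimum or one of 100, an additive expectation, scores scaled by the spread of non-targeting pairs, a z-score against non-targeting pseudo-genes, each sgRNA order alone, no replicate block, the authors' deposited phenotypes, and each replicate left out. The sgRNA and tripleseq readouts, a minimum of 35 T0 reads per construct, and Jurkat replicate numbers crossed were added after the data were seen.

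The tests were tried on simulated data made from the real means. For the growth effects, 100% of 50 genes at each planted log2 change of −2, −1, 1 and 2 were recovered in each line, and 0.738% of unchanged genes were called in K562 and 2.21% in Jurkat. For interactions in the shared fit, planted scores of −2 and 2 were recovered in 97.1% and 93.9% of pairs in K562 and in 100% and 97.0% in Jurkat, and those of −1 and 1 in 14.7% and 39.4% in K562 and 14.7% and 30.3% in Jurkat. Of the planted scores of −0.5 and 0.5, 3.03% and 0% were recovered in K562 and 0% of either in Jurkat. Scores of ±2 were added after the smaller ones had been recovered so rarely. Simulated unchanged pairs had an unadjusted p below 0.05 in 12.2% of cases in K562 and 1.36% in Jurkat, so the shared fit is too liberal for K562 and too strict for Jurkat. Fitted alone, these shares were 6.93% and 5.78%, and planted scores of −1 and 1 were recovered in 26.5% and 54.5% of pairs in K562 and in 100% and 97.0% in Jurkat.

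A gene table of the assembly GRCh38, which differs from the submitters' hg19, was used only to find which genes are neighbours; 464 of 469 gene symbols matched it, and no coordinates are given. GEMIN8 and HSPA5 were among the genes lost to the T0 minimum and are not on the interaction maps. Some genes and pairs met the rule for naming but are not reported here, and they stay in every fit and count.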

Results

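Growth effects of single genes and genetic interactions of gene pairs were measured by pooled CRISPR interference in K562, a chronic myeloid leukemia line, and in Jurkat, a T-cell leukemia line. Each construct represses 2 targets at once, and its change in abundance over 10 days reports how fast the cells that carry it multiply. The library paired 1022 sgRNAs with each other in both orders, giving 1044484 constructs. There were 2 replicate libraries in each of 4 groups, and every estimate below rests on 2 replicates per group. The barcode readout held 438077705 and 489135711 reads in K562 T0 replicates 1 and 2, and 527093397 and 430138312 in the K562 Endpoint replicates. Jurkat T0 held 634558090 and 538272796 reads, and Jurkat Endpoint 456747566 and 473297933. The median construct had 311 and 343 reads in K562 T0, 244 and 202 in K562 Endpoint, 447 and 377 in Jurkat T0, and 234 and 243 in Jurkat Endpoint.

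Repression of nearly every gene of the library slowed K562 cells. The lowest growth effect belonged to EIF2B2, a subunit of the translation factor eIF2B, at −4.40 ± 0.11 (log2 of endpoint over T0 ± SE, relative to non-targeting constructs). DUT, the dUTPase that keeps uracil out of DNA, followed at −4.35 ± 0.12. The other lowest genes encode cytosolic ribosomal proteins, spliceosome parts and a membrane fusion protein. The ribosomal genes were RPL38 at −4.17 ± 0.13, RPL30 at −4.00 ± 0.10, RPS10-NUDT3 at −3.98 ± 0.13 and RPS14 at −3.92 ± 0.11. The spliceosome genes were the U5 snRNP helicases DDX23, at −4.11 ± 0.14, and SNRNP200, at −3.85 ± 0.19, and the SF3b subunit PHF5A, at −3.97 ± 0.11. BNIP1, a SNARE of the ER, lay at −3.96 ± 0.08. Of 471 genes tested with edgeR, 464 fell and 1 rose at an adjusted p below 0.05, and 422 fell by at least 1 (465 at an unadjusted p below 0.05).

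For comparison, 16 non-targeting sgRNAs taken as genes had an SD of 0.077 in K562 and 0.059 in Jurkat, and ranged from −0.15 to 0.15 and from −0.094 to 0.11. The only K562 gene called above 0 was RPL35, at 0.15 ± 0.06 (adjusted p = 0.032), measured with 1 sgRNA and within the range of the non-targeting sgRNAs. Its call was lost with K562 T0 replicate 1 left out (adjusted p = 0.0835), and likewise without K562 T0 replicate 2 (0.116), K562 Endpoint replicate 1 (0.109), Jurkat T0 replicate 1 (0.0676) and Jurkat T0 replicate 2 (0.0673), and in the sgRNA readout its effect was 0.03. The weakest depletions past the threshold were ZNF598 at −0.28 ± 0.07, C6orf203 at −0.29 ± 0.05, SFXN1 at −0.31 ± 0.08 and EMC1 at −0.31 ± 0.06. The 2 sgRNAs of C6orf203 differed, at −3.48 and 0.03. The direction of such weak effects depends on the scale. TMM, which centres on the typical gene, moved the median gene of K562 by 2.21 and that of Jurkat by 0.66. It gave 217 genes lower and 195 higher in K562, while DESeq2 with its own size factors gave 213 and 197.

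By gene list, the lowest K562 medians were those of translation initiation and elongation and of DNA replication. Translation initiation and elongation fell in 12 of 12 genes with a median of −2.97, DNA replication in 17 of 17 with −2.91, splicing in 20 of 20 with −2.71, cytosolic aminoacyl-tRNA synthetases in 9 of 9 with −2.69 and mitochondrial ribosome and translation in 44 of 44 with −2.68, and under TMM these medians stayed below 0, at −0.76, −0.70, −0.51, −0.48 and −0.48. In the cytosolic ribosome 24 of 25 genes fell and RPL35 rose, with a median of −2.73 that stayed at −0.53 under TMM. Medians that also stayed below 0 under TMM were those of the proteasome (9 of 9 fell, −2.59), ER-Golgi trafficking (7 of 7, −2.58), Mediator and RNA polymerase II (20 of 20, −2.48), mitosis and cell cycle (28 of 28, −2.46), mTORC1 and growth control (6 of 6, −2.35), ribosome biogenesis (19 of 19, −2.34) and the V-ATPase (3 of 3, −2.34). Shallower lists lay above the typical gene, so that their medians turned positive under TMM: RNA decay and export (21 of 21 fell, −2.12), DNA damage checkpoint and repair (8 of 8, −2.11), respiratory complexes III and IV and ATP synthase (9 of 9, −2.01), chromatin (4 of 4, −1.95) and respiratory complex I (6 of 6, −1.86). The same held for mitochondrial import (11 of 11, −1.85), nucleotide synthesis (5 of 6, −1.69), heme and iron-sulfur clusters (4 of 4, −1.54), mevalonate and cholesterol synthesis (3 of 3, −1.52) and ER protein entry (8 of 9, −0.45), whose medians under TMM were 0.35, 0.51, 0.66, 0.69 and 1.76. Adjusted over the list alone, every K562 count was the same. ER protein entry was the only list that camera set apart from the other genes in K562, as less depleted (adjusted p = 0.000504), and this was lost with an estimated correlation (adjusted p = 0.999). The chaperonin list had 2 measured genes, with a median of −2.44 in K562 and −0.25 in Jurkat, and was not tested.

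In Jurkat, CDCA8, a member of the chromosomal passenger complex, was lowest at −3.05 ± 0.10, against −3.21 in K562. Next were NSMCE1 of the SMC5/6 complex at −2.88 ± 0.13 and the TFIID subunit TAF2 at −2.79 ± 0.08. The cytokinesis genes CIT and KIF14 lay at −2.74 ± 0.09 and −2.72 ± 0.11, the dynactin subunit DCTN2 at −2.63 ± 0.11 and the replication fork protein TIMELESS at −2.63 ± 0.10. RPS14 (−2.76 ± 0.11), RPL38 (−2.71 ± 0.12) and C9orf114 (−2.63 ± 0.09) completed the 10 lowest, and RPS14 and RPL38 were also among the 10 lowest of K562. In edgeR 388 of 471 genes fell in Jurkat and 0 rose (392 at an unadjusted p below 0.05), 155 of them by at least 1. With DESeq2 and non-targeting size factors 391 fell and 0 rose. With TMM 190 fell and 194 rose, and with DESeq2's own size factors 179 fell and 218 rose. Requiring every sgRNA of a gene to pass alone left 258 lower genes.

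The weakest Jurkat calls were EFR3A at −0.11 ± 0.05, C6orf203 at −0.13 ± 0.05, SKIV2L2 at −0.14 ± 0.05, C11orf30 at −0.14 ± 0.06 and GPN3 at −0.15 ± 0.05, and all turned positive under TMM. Several were much lower in K562: EFR3A at −2.22, SKIV2L2 at −2.55 and GPN3 at −3.35. GPN3 lost its call without Jurkat T0 replicate 2 (adjusted p = 0.147) or Jurkat Endpoint replicate 2 (0.129). SKIV2L2 lost it without Jurkat T0 replicate 1 (0.15), Jurkat T0 replicate 2 (0.0505) or Jurkat Endpoint replicate 1 (0.212). C11orf30 lost it without K562 T0 replicate 1 (0.0505), K562 T0 replicate 2 (0.0504), Jurkat T0 replicate 1 (0.252) or Jurkat Endpoint replicate 1 (0.188). EFR3A and C6orf203 lost theirs without any 1 of the T0 libraries or of the Jurkat Endpoint libraries, with adjusted p up to 0.242 and 0.214, both without a Jurkat T0 library (replicate 2 for EFR3A, replicate 1 for C6orf203), and the lowest at 0.0715 and 0.0581 without a K562 T0 library.

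Among the gene lists in Jurkat, the cytosolic ribosome (23 of 25 fell, median −1.66), splicing (18 of 20, −1.66), nucleotide synthesis (5 of 6, −1.61), DNA replication (16 of 17, −1.55) and ER-Golgi trafficking (5 of 7, −1.55) were lowest. Under TMM the medians of all 5 stayed below 0, those of the last 3 at −0.95, −0.89 and −0.90. Heme and iron-sulfur clusters (3 of 4, −1.27), chromatin (3 of 4, −1.10), DNA damage checkpoint and repair (8 of 8, −1.08), translation initiation and elongation (11 of 12, −0.83), mitosis and cell cycle (23 of 28, −0.77) and ribosome biogenesis (17 of 19, −0.76) likewise stayed below 0 under TMM. For Mediator and RNA polymerase II (16 of 20, −0.73), RNA decay and export (21 of 21, −0.72), the proteasome (9 of 9, −0.69) and aminoacyl-tRNA synthetases (8 of 9, −0.66), the sign differed between TMM and DESeq2's own size factors or lay at 0. The following medians turned positive under TMM: mitochondrial ribosome and translation (42 of 44, −0.55), complex I (6 of 6, −0.56), mitochondrial import (8 of 11, −0.38), complexes III and IV and ATP synthase (4 of 9, −0.19), mTORC1 and growth control (3 of 6, −0.22), the V-ATPase (1 of 3, −0.14), mevalonate synthesis (2 of 3, −0.44) and ER protein entry (5 of 9, −0.15). Adjusted over the list alone, 3 genes fell in complexes III and IV and ATP synthase and 4 in ER protein entry, and the other counts were the same. Camera set DNA replication apart as more depleted than other genes (adjusted p = 0.0375), which did not hold with an estimated correlation (adjusted p = 0.999).

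**Figure D1:**
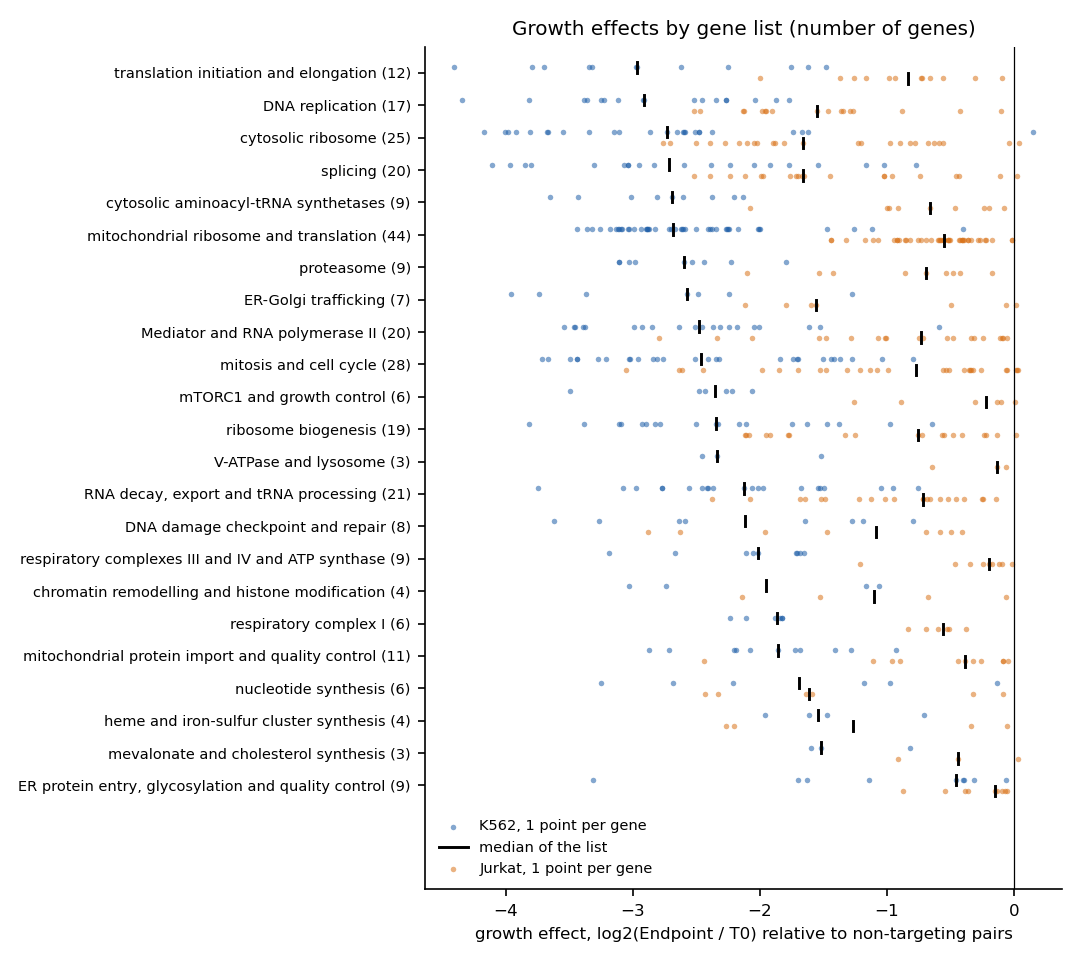
Growth effects (log2 of Endpoint over T0, relative to constructs with 2 non-targeting sgRNAs) of the genes of each list, with 1 point per gene for K562 (blue) and Jurkat (orange) and a black bar at each list's median. K562 medians run from −2.97 for translation initiation and elongation to −0.45 for ER protein entry, and under TMM, which moves K562 by 2.21 and Jurkat by 0.66, the medians of the lists from RNA decay downward turn positive in K562.

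Setting the lines against each other asked which genes each cell type depends on more. Most genes were depleted less in Jurkat: 424 of 471 had a less negative growth effect there and 15 a more negative one, by a test of the difference itself (edgeR, 439 at an unadjusted p below 0.05). On the non-targeting scale DUT differed most, at −4.35 in K562 and −0.88 in Jurkat (difference 3.47 ± 0.16). With Jurkat effects divided by the slope its difference was 2.09, below that of DYNC1H1 (3.28). The dynein heavy chain DYNC1H1 lay at −3.44 in K562 and −0.06 in Jurkat (3.38 ± 0.09), GPN3, an assembly factor of RNA polymerase II, at −3.35 and −0.15 (3.21 ± 0.07), and CDC27 of the anaphase-promoting complex at −3.50 and −0.35 (3.14 ± 0.08). POLR2B, a subunit of RNA polymerase II, differed by 2.92 ± 0.09, SNRNP200 by 2.89 ± 0.25 and the TFIIIB subunit BDP1 by 2.86 ± 0.09. EIF4G2, a translation factor, differed by 3.25 ± 0.22, but this rested on 1 of its sgRNAs, since the other had few reads at T0.

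Of the genes more depleted in Jurkat, the SR splicing factor SRSF7 differed most and fell to −2.51 in Jurkat against −1.17 in K562 (difference −1.35 ± 0.08). NUBP1, a cytosolic iron-sulfur assembly factor, differed by −0.59 ± 0.15 (−2.20 against −1.61). Further genes were DHX37 (−0.64 ± 0.12), GEMIN2 of the SMN complex (−0.62 ± 0.15), the U1-associated LUC7L3 (−0.58 ± 0.10), the nuclear exonuclease XRN2 (−0.54 ± 0.17, adjusted p = 0.012) and KIF14 (−0.50 ± 0.15). XRN2 lost its call without K562 T0 replicate 2 (−0.47) or Jurkat Endpoint replicate 1 (−0.45). The differences of DHX37, GEMIN2, LUC7L3, KIF14 and EIF4G2 were lost when every sgRNA of a gene had to pass alone. NUBP1 and XRN2 had 1 sgRNA each, so for them this check added no other sgRNA. GFI1B, the erythroid repressor and the only measured gene of the K562 lineage list, fell to −1.95 ± 0.08 in K562 and was 0.08 in Jurkat (adjusted p = 0.358), a difference of 2.02. None of the T-lineage list was measured (0 genes).

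**Figure D2:**
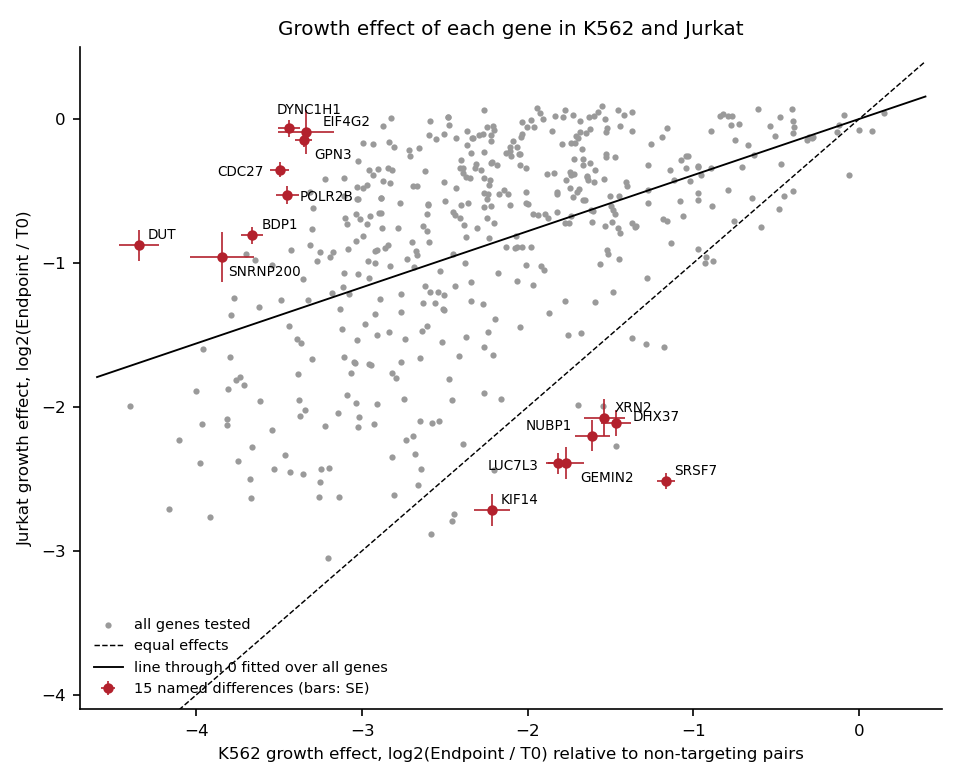
Growth effect of each of the 471 genes in K562 (x axis) and Jurkat (y axis), both as log2 of Endpoint over T0 relative to constructs with 2 non-targeting sgRNAs; red points with SE bars are the 15 named differences, the solid line is fitted through 0 and the dashed line marks equal effects. The fitted slope is 0.390, with DUT at −4.35 and −0.88 above it and SRSF7 at −1.17 and −2.51 below it.

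Across genes, Jurkat effects followed K562 effects with Pearson's r = 0.50 and Spearman's rho = 0.51 and a slope through 0 of 0.390 (0.387 and 0.392 in replicates 1 and 2). Genes are not independent replicates, and replicates of a line correlated at r = 0.98 in both lines. The direction of the differences also depends on scale: TMM gave 217 genes more and 164 less depleted in Jurkat, DESeq2's own size factors 201 and 177, and division of Jurkat effects by the slope 154 and 216. Less depleted in Jurkat than in K562, by medians on the non-targeting scale and under TMM, were mTORC1 and growth control (6 of 6 genes higher, median difference 2.20 and under TMM 0.64), aminoacyl-tRNA synthetases (9 of 9, 2.13 and 0.58), mitochondrial ribosome and translation (44 of 44, 2.04 and 0.49), translation initiation and elongation (12 of 12, 2.02 and 0.48), ER-Golgi trafficking (7 of 7, 1.94 and 0.39), Mediator and RNA polymerase II (18 of 20, 1.83 and 0.28), the V-ATPase (3 of 3, 1.80 and 0.25), the proteasome (9 of 9, 1.74 and 0.18) and complexes III and IV and ATP synthase (9 of 9, 1.67 and 0.13). Division of Jurkat effects by the slope split several of these lists. ER-Golgi trafficking had SEC22B at 2.53 and COG3 at 2.10 but USE1 at −2.85 and COPA at −0.87. Mediator and RNA polymerase II ranged from TAF2 at −4.71 to MED10 at 2.23. The proteasome ranged from PSMC6 at −2.84 to PSMD12 at 1.74, and aminoacyl-tRNA synthetases from MARS at −2.30 to KARS at 2.31. Medians above 0 that turned below 0 under TMM were those of the cytosolic ribosome (24 of 25 higher, 1.38), complex I (6 of 6, 1.36), mitochondrial import (8 of 11, 1.34), splicing (17 higher and 3 lower of 20, 1.32), mitosis (24 of 28, 1.30), ribosome biogenesis (16 of 19, 1.27), DNA replication (17 of 17, 1.08), RNA decay (19 of 21, 1.08), chromatin (4 of 4, 0.99), mevalonate synthesis (3 of 3, 0.86), DNA damage (7 of 8, 0.67), nucleotide synthesis (4 of 6, 0.46) and ER protein entry (6 of 9, 0.34). Heme and iron-sulfur clusters had 2 genes higher and 2 lower, with a median of −0.11 (−1.66 under TMM) and a mean of 0.22. Adjusted over the list alone these counts were the same. Against other genes, camera placed the difference lower for heme and iron-sulfur clusters (adjusted p = 0.00292) and nucleotide synthesis (0.0471), although the latter's median was above 0, and higher for mitochondrial ribosome and translation (0.0471), and none held with an estimated correlation (adjusted p = 0.999).

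Genetic interactions asked which pairs of genes, repressed together, slowed K562 more or less than their single effects predict. The lowest score belonged to LEO1, of the Paf1 transcription complex, with the ER SNARE USE1, at −2.21 ± 0.20 (log2 ± SE, adjusted p = 0.011). ATP6AP1, an accessory V-ATPase subunit, with EMC2 of the ER membrane complex lay at −2.13 ± 0.20. DONSON, a replication fork gene, interacted negatively with GNL3L (−2.12 ± 0.26) and with the ribosome rescue factor PELO (−1.99 ± 0.30). The dUTPase DUT with the ribosomal stalk gene RPLP1 scored −2.02 ± 0.20 and EIF3H with NUTF2 −1.89 ± 0.23. ERH with SLC39A9 (−2.11 ± 0.11) and CENPK with PPWD1 (−1.92 ± 0.27) are pairs of neighbouring genes in the GRCh38 assembly.

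Among the positive K562 pairs, a kinase and the phosphatase it opposes stood out by function: MASTL with PPP2R1A, the scaffold of PP2A, scored 1.45 ± 0.14. EXOSC3 of the RNA exosome with SNRPG scored 1.73 ± 0.16, NOL8 with RPL23 1.63 ± 0.21, DONSON with NUTF2 1.62 ± 0.22 and MZT1 with the SUMO-activating enzyme UBA2 1.53 ± 0.17. DCTN2 with RPL34 (1.42 ± 0.19), CDK1 with EIF4G2 (1.41 ± 0.23) and MED10 with RBM22 (1.03 and 1.78 in the replicates) completed the 8 highest. In all, limma called 1709 negative and 2247 positive pairs of 109746 in K562 (26051 at an unadjusted p below 0.05). All 3956 had the same sign in both replicates, but the threshold fixed this in advance. Replicates of opposite sign would give too large a spread to pass, so it is no evidence of reproducibility. The spread shared between the lines made this test liberal in K562: of 3752 pairs of a gene with a non-targeting pseudo-gene, 8.53% had an unadjusted p below 0.05. Of the 3752, 10 (0.267%) fell below the p limit of the calls, against 3.60% of gene pairs. The 3752 pairs share genes and 16 non-targeting sgRNAs, so the exact 95% interval of 0.128 to 0.490, which takes them as independent, is likely too narrow. Simulated unchanged pairs had an unadjusted p below 0.05 more often (12.2%), so pairs with pseudo-genes may understate the spread of gene pairs. With K562 fitted alone 603 negative and 722 positive pairs passed, and MED10 with RBM22 lost its call (adjusted p = 0.0542). Leaving out either Jurkat replicate gives this same K562 fit, since the lone Jurkat sample adds no spread, and so is no further check. Counts rose to 8397 and 9362 without K562 replicate 1 and to 13160 and 14790 without K562 replicate 2. The sum of single effects as expectation, in place of the fitted curve, gave 310 negative and 98989 positive pairs and turned EIF3H with NUTF2 positive (0.34).

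In Jurkat no pair passed in the shared fit (0 negative and 0 positive by limma, 3078 at an unadjusted p below 0.05), whereas Jurkat fitted alone gave 161 negative and 171 positive pairs (10894 at an unadjusted p below 0.05), the z-score against non-targeting pseudo-genes 1999 and 2323, and the authors' deposited phenotypes 4 and 3. Leaving out either K562 replicate gives the same Jurkat fit as Jurkat alone, since the lone K562 sample adds no spread, and so is no further check. The shared fit was strict here, with 0.959% of pairs with non-targeting pseudo-genes at an unadjusted p below 0.05. The following pairs were taken from the fit of Jurkat alone and so were chosen after their values were seen. The lowest were METTL17 with RAE1 (−1.68), PELO with WDR61 (−1.30), LEO1 with WDR61 (−1.29), MRPL13 with MTBP (−1.14) and COX5A with RPL35 (−1.11), and then ATP5F1 with WDR77 (−0.99), RPL23 with RPL24 (−0.95) and NUBP1 with TAF2 (−0.91). WDR61 is shared by the Paf1 and SKI complexes. The highest were BDP1 with GEMIN2 (1.15), DCTN2 with EIF4G2 (1.13), CDC16 with SGOL1 (0.96), SPAG7 with UBA2 (0.96), EIF4G2 with PPP2R2A (0.93), BDP1 with C9orf114 (0.92), CDC40 with EIF4G2 (0.90) and GFER with NUTF2 (0.90, or 0.55 without Jurkat replicate 1). An additive expectation turned RPL23 with RPL24 (0.22) and NUBP1 with TAF2 (0.42) positive.

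Several pairs interacted in both lines when each line was fitted alone, again chosen after their values were seen. LEO1 with WDR61, both of the Paf1 complex, scored −1.64 in K562 and −1.29 in Jurkat, and PELO with WDR61 −0.93 and −1.30. NCBP1 with NUDC scored −0.81 and −0.75, and CENPK with PPWD1 −1.92 and −0.83. UBA2 was less harmful than predicted beside SPAG7 (0.87 and 0.96), C9orf114 (0.78 and 0.76) and GEMIN2 (0.68 and 0.75), as was SNAPC1, a factor of snRNA transcription, beside DMAP1 (1.05 and 0.88) and RPSA (0.97 and 0.69). In all, 25 negative pairs were shared where independent lists would share 0.885, 51 positive pairs were shared against 1.12, and 1 pair had opposite signs. An additive expectation turned PELO with WDR61 (0.044) and NCBP1 with NUDC (0.83) positive in K562.

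**Figure D3:**
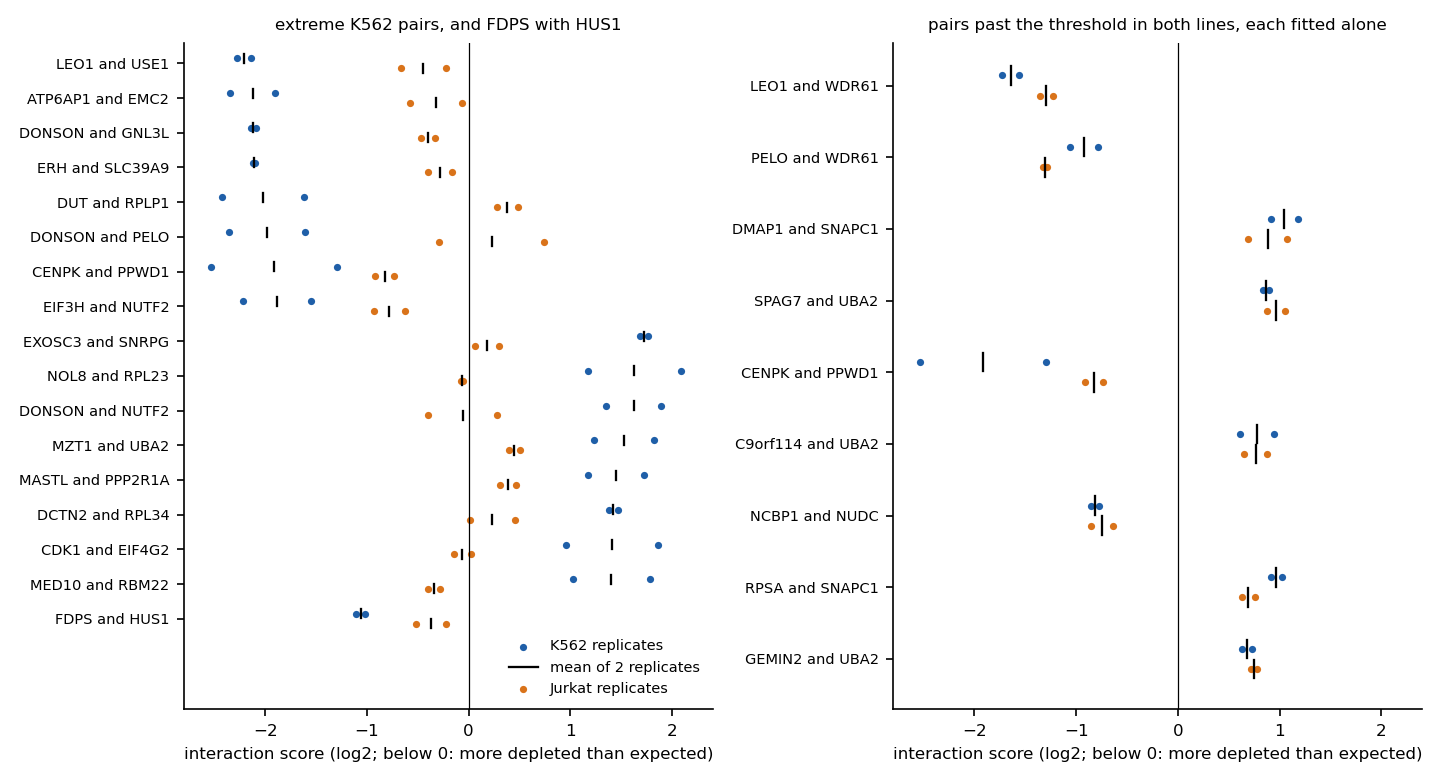
Interaction scores (x axis, log2; below 0 the pair was more depleted than its expectation) of the 16 extreme K562 pairs and of FDPS with HUS1 (left), and of 9 pairs past the threshold in both lines fitted alone (right), with a point for each replicate of K562 (blue) and Jurkat (orange) and a bar at their mean. LEO1 with USE1 lies at −2.21 in K562 and −0.45 in Jurkat, while LEO1 with WDR61 lies at −1.64 and −1.29.

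A pair named before the data were examined here, because the study is known for it, joins mevalonate synthesis to the DNA damage response. Since the link is known from the study that produced these data, its test here is not an independent one. FDPS, farnesyl diphosphate synthase, and HUS1, part of the DNA damage checkpoint clamp, interacted negatively in K562 with a score of −1.06 ± 0.12 (replicates −1.10 and −1.02, adjusted p = 0.0135, and 0.0152 with K562 fitted alone). In Jurkat the score was −0.37, with replicates at −0.51 and −0.23, and did not pass (adjusted p = 1, and 0.172 with Jurkat fitted alone), although the z-score test called it (adjusted p = 0.0149). The difference between the lines did not pass either (adjusted p = 0.25). Alone, FDPS had growth effects of −1.60 in K562 and −0.44 in Jurkat, and HUS1 −1.28 and −0.58, all of which turned positive under TMM. The Jurkat effect of HUS1 was −0.95 and −0.24 in the replicates, and −0.35 without Jurkat Endpoint replicate 1. With only the constructs in which HUS1 stands first, the K562 call was lost (adjusted p = 0.0579).

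Comparing the interaction maps asked how far the lines share interactions. No pair differed between the lines in the shared fit (limma, 0 negative and 0 positive, 13411 at an unadjusted p below 0.05), while the z-score gave 3298 and 4177. The shared fit gave 3623 and 3463 without K562 replicate 1 and 7999 and 7227 without K562 replicate 2, and 0 and 0 without either Jurkat replicate. Scores correlated between lines at r = 0.147 and rho = 0.135 across 109746 pairs, which are not independent. Gene labels permuted 10000 times gave at most r = 0.0192 (one-sided p = 0.0001, the smallest they can give). Single replicates correlated at r = 0.284 within K562 and 0.185 within Jurkat. The 0.147 between lines is for means of 2 replicates, so it cannot be set directly against these values. Leaving out 1 replicate lowered it to between 0.105 and 0.127. Scores had an SD of 0.298 in K562 and 0.144 in Jurkat. Of the K562 calls, 68.2% had the same sign in Jurkat, against 54.3% of all pairs.

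At the level of gene lists, the mitochondrial ribosome and respiratory lists had positive mean scores among themselves in K562, and the mitochondrial import list did not (−0.0034 with the mitochondrial ribosome, −0.060 with complex I and −0.037 with complexes III and IV and ATP synthase, none of which passed). The 946 pairs within mitochondrial ribosome and translation had a mean score of 0.38, with 94.8% of pairs above 0 and 182 positive calls (42 with K562 fitted alone), among them MRPL19 with MRPS18B at 1.09 and MRPL11 with MRPS5 at 1.03. Complex I scored positively within itself (0.39) and with complexes III and IV and ATP synthase (0.34), as did the mitochondrial ribosome with complexes III and IV and ATP synthase (0.26, for example ATP5F1 with MRPS11 at 0.82) and with complex I (0.14). NDUFA8 with NDUFA9 (0.81) and NDUFA8 with NDUFB2 (0.83) are examples within complex I. Both lost their call with K562 fitted alone, the same fit as with either Jurkat replicate left out (adjusted p = 0.0505 and 0.0815). Negative means joined mitochondrial genes with growth control. The mTORC1 and growth control list, which is broader than mTORC1, scored −0.40 with complex I (MAX with NDUFA8 at −1.01). It scored −0.26 with the mitochondrial ribosome (MAPKAP1 with MRPL27 at −1.07) and −0.21 with complexes III and IV and ATP synthase. MAPKAP1 with MRPL27 lost its call with K562 fitted alone, the same fit as with either Jurkat replicate left out (adjusted p = 0.0575). The proteasome scored −0.19 with the mitochondrial ribosome (MRPL11 with PSMC1 at −1.09) and 0.22 with aminoacyl-tRNA synthetases. By permutation of gene labels, 33 of 231 list pairs passed in K562, 17 of them lower and 16 higher.

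Outside mitochondria, K562 genes of the DNA damage checkpoint scored −0.25 with DNA replication genes over 136 pairs, with 13 negative calls (9 with K562 fitted alone). Examples were HUS1 with POLD3 (−1.33) and with POLE (−1.31), and MCM4 with TIPIN (−1.26). Heme and iron-sulfur genes scored −0.65 among themselves over 6 pairs. ER-Golgi trafficking genes scored −0.26 among themselves (BNIP1 with COPA at −1.10) and −0.19 with ER protein entry (ASNA1 with SEC22B at −0.96), the former lost without K562 replicate 1 (adjusted p = 0.475) and the latter without K562 replicate 2 (0.0685). DNA replication scored 0.12 with splicing, and nucleotide synthesis 0.16 with RNA decay. Measured from the mean of permuted gene labels, an additive expectation moved the mitochondrial ribosome with mTORC1 and with the proteasome, and ER-Golgi trafficking within itself, from below to above it, and nucleotide synthesis with RNA decay from above to below it (by −0.033). Of the named pairs it turned MRPL11 with PSMC1, MAPKAP1 with MRPL27, MAX with NDUFA8, MCM4 with TIPIN, BNIP1 with COPA and ASNA1 with SEC22B positive.

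In Jurkat the same test passed 19 of 231 list pairs, 6 lower and 13 higher, but 9 without Jurkat replicate 1 and 5 without Jurkat replicate 2. The mitochondrial ribosome scored 0.079 within itself and 0.077 with complex I, Mediator and RNA polymerase II −0.073 within itself, and ribosome biogenesis −0.045 with mitosis, all of which passed without either replicate. Heme and iron-sulfur genes again scored below 0 among themselves, at −0.24, which did not pass without Jurkat replicate 1 (adjusted p = 0.0796) or Jurkat replicate 2 (0.161). With an additive expectation, the Jurkat means of the mitochondrial ribosome within itself and with complex I fell to about the mean of permuted gene labels (−0.0025 and −0.0038 from it), and ribosome biogenesis with mitosis lay 0.029 above it. A permutation test of the difference, added after the data were seen, found 23 of 231 list pairs to differ between the lines. Scores were not scaled for their spread, which was larger in K562 (SD 0.298) than in Jurkat (0.144). By this test a difference in scale and a changed relation between lists therefore cannot be told apart. The checkpoint and replication lists differed by 0.29 (Jurkat minus K562) and mTORC1 and growth control with complex I by 0.33, the latter lost with an additive expectation (adjusted p = 0.526), whereas 7 list pairs passed in both lines, all 7 with the same sign.

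**Figure D4:**
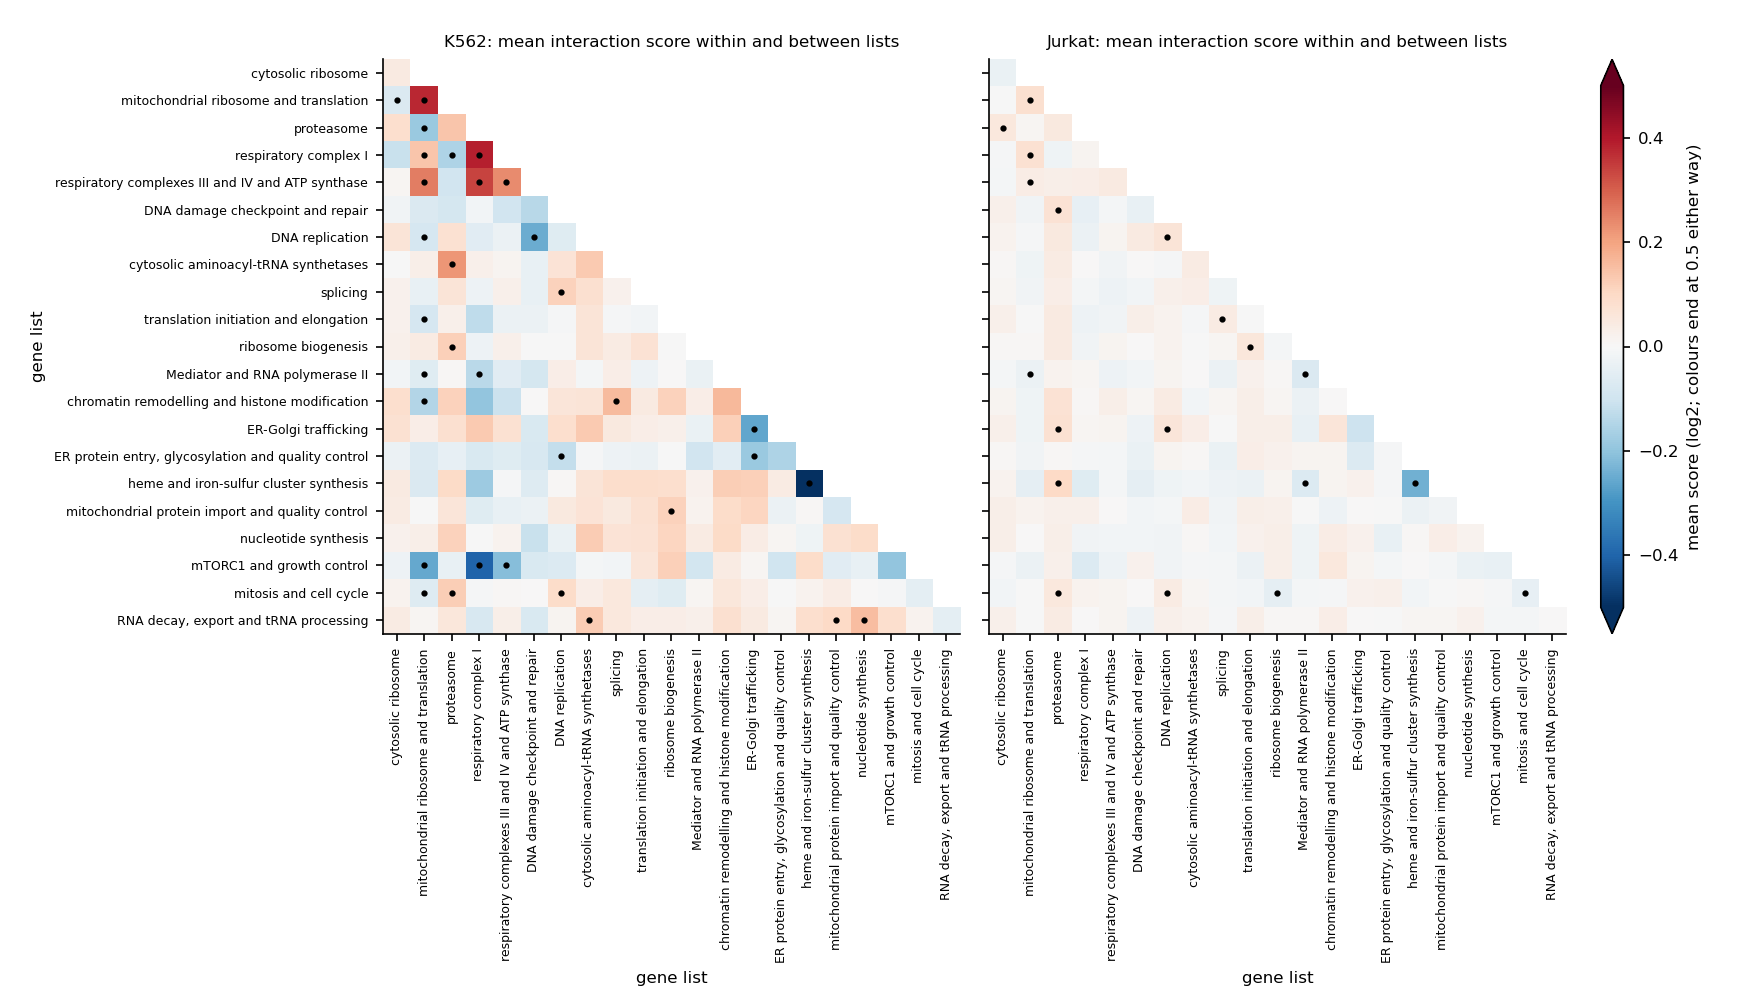
Mean interaction score (colour, log2; red above 0, less depleted than expected; blue below 0) within and between gene lists in K562 (left) and Jurkat (right), with a dot where the mean passed the permutation test. In K562 the mitochondrial ribosome list reaches 0.38 within itself, and mTORC1 and growth control with complex I −0.40, while the corresponding Jurkat means are 0.079 and −0.070. The K562 mean of the mitochondrial ribosome with mTORC1 and growth control, −0.26, lies above that of permuted gene labels with an additive expectation.

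Genes of a complex also had similar interaction profiles. Mean profile correlations within lists passed in 14 of 21 lists in K562 and in 12 of 21 in Jurkat (one-sided permutation test; means of 0.417 and 0.153 for the mitochondrial ribosome, 0.302 and 0.131 for complex I, 0.297 and 0.100 for the proteasome, and 0.231 and 0.156 for ER-Golgi trafficking). DNA replication stood at 0.223 and 0.079 and the cytosolic ribosome at 0.117 and 0.086. For comparison, permuted gene labels gave means of 0.069 and 0.045 for DNA replication and of 0.070 and 0.045 for the cytosolic ribosome. Complexes III and IV and ATP synthase (0.277), mTORC1 (0.248), chromatin (0.219) and aminoacyl-tRNA synthetases (0.208) passed in K562, and nucleotide synthesis (0.118) and Mediator and RNA polymerase II (0.103) in Jurkat; the difference between lines was not tested. Without Jurkat replicate 1 the Jurkat count was 5, without Jurkat replicate 2 it was 10, and an additive expectation left 4 lists in K562 and 2 in Jurkat.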

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

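The tests of doublings, of a common factor, of a shared spread and of read depth, and the tests of list differences in interaction scores, were chosen only after the results were seen.

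The growth effects of single genes differed between the lines by a test of the difference itself, with 424 genes less and 15 more depleted in Jurkat on the non-targeting scale. Under TMM 164 were less and 217 more depleted in Jurkat, with DESeq2's own size factors 177 and 201, and with Jurkat effects divided by the slope 216 and 154. On the non-targeting scale, less depleted in Jurkat by the largest margins were DUT (3.47, log2, Jurkat minus K562), DYNC1H1 (3.38), EIF4G2 (3.25), GPN3 (3.21), CDC27 (3.14), POLR2B (2.92), SNRNP200 (2.89) and BDP1 (2.86). More depleted in Jurkat were SRSF7 (−1.35), DHX37 (−0.64), GEMIN2 (−0.62), NUBP1 (−0.59), LUC7L3 (−0.58), XRN2 (−0.54) and KIF14 (−0.50). Among lists, camera found differences for heme and iron-sulfur clusters (median −0.11 on the non-targeting scale and −1.66 under TMM), nucleotide synthesis (0.46, and −1.08 under TMM) and mitochondrial ribosome and translation (2.04, and 0.49 under TMM). None held with an estimated correlation (adjusted p = 0.999).

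Mean interaction scores of 23 list pairs differed between the lines by permutation of gene labels. That test sets a list against other genes and does not measure the spread between replicates. Scores were not scaled between the lines, although their SD was 0.298 in K562 and 0.144 in Jurkat. The test thus cannot tell a difference in scale from a changed relation between lists. Within mitochondrial ribosome and translation the difference (Jurkat minus K562, log2) was −0.30. This list also differed in its scores with complexes III and IV and ATP synthase (−0.22), the proteasome (0.19), mTORC1 and growth control (0.23), translation initiation and elongation (0.080), DNA replication (0.077), the cytosolic ribosome (0.069) and mitosis (0.060). Complex I differed within itself (−0.38) and with complexes III and IV and ATP synthase (−0.31), mTORC1 (0.33) and Mediator and RNA polymerase II (0.15), and mTORC1 with complexes III and IV and ATP synthase by 0.19. DNA replication differed with the DNA damage checkpoint (0.29), within itself (0.12), with ER protein entry (0.14) and with splicing (−0.088). The remaining differences were the proteasome with DNA damage (0.16) and with aminoacyl-tRNA synthetases (−0.18), aminoacyl-tRNA synthetases with RNA decay (−0.11), nucleotide synthesis with RNA decay (−0.13), splicing with chromatin (−0.15), and Mediator and RNA polymerase II with ER protein entry (0.11).

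Of these 23 differences, 6 lost their call without K562 replicate 1, 6 without K562 replicate 2, 1 without Jurkat replicate 1 and 3 without Jurkat replicate 2. Without K562 replicate 1 these were the mitochondrial ribosome with translation (adjusted p = 0.0628), DNA replication within itself (0.112) and with splicing (0.0628), splicing with chromatin (0.0855), Mediator with ER protein entry (0.0525), and nucleotide synthesis with RNA decay (0.0938). Without K562 replicate 2 they were the proteasome with DNA damage (0.146), complexes III and IV and ATP synthase with mTORC1 (0.0813), DNA replication with ER protein entry (0.0862), aminoacyl-tRNA synthetases with RNA decay (0.254), splicing with chromatin (0.0813) and Mediator with ER protein entry (0.116). Mediator with ER protein entry was also lost without Jurkat replicate 1 (0.0616). Without Jurkat replicate 2 the mitochondrial ribosome with translation (0.0554), the proteasome with DNA damage (0.0841) and splicing with chromatin (0.0849) were lost. Measured from the mean of permuted gene labels, 8 reversed with an additive expectation, namely the mitochondrial ribosome with the cytosolic ribosome, proteasome, DNA replication, translation, mTORC1 and mitosis, complexes III and IV and ATP synthase with mTORC1, and nucleotide synthesis with RNA decay, and 9 lost their call.

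On the non-targeting scale, the slope through 0 of Jurkat on K562 growth effects was 0.390. The median effect was −0.66 in Jurkat and −2.26 in K562. Of the growth correlation and the slope between the lines, 1 moved beyond the spread of replicates under TMM, DESeq2's own size factors and the sgRNA readout. In the tripleseq readout 2 moved. Fewer doublings of Jurkat are argued against as the whole cause, because after division by the doublings that the constants in the authors' deposited table would imply, the slope was still 0.449 (0.435 and 0.463 in the replicates). Growth effects smaller by 1 common factor in Jurkat would leave few differences after division by the slope, yet 78.6% of genes still differed. This argues against 1 common factor of growth effects. A weaker knockdown in Jurkat stays open, since growth effects need not be proportional to knockdown in every gene. A constant shift from scaling to the non-targeting constructs stays open, since a free intercept gave a slope of 0.417 (0.404 and 0.427), but with r = 0.504 between the lines even equal spreads would give only 0.504, so this test could not decide. A mixture of such causes, or a biological difference between the lines, which was not tested apart from them, may also remain. T0 also differed, at day 5 after infection for K562 and day 6 for Jurkat, and this cannot be told apart from the line.

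Interaction calls were 3956 in K562 and 0 in Jurkat in the shared fit. A spread estimate shared with the noisier K562 maps may account for the absence, since Jurkat fitted alone gave 332 calls and the share of non-targeting pairs at an unadjusted p below 0.05 was 8.53% in K562 and 0.959% in Jurkat. Fewer reads in Jurkat are argued against, because its libraries' mean of median reads per construct was 325 against 275 in K562, a ratio of 1.18. The larger spread of scores in K562 (SD 0.298 against 0.144) with its larger growth effects, and a biological difference between the lines, stay open and were not tested.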

How the results depend on the processing

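The readouts, crossed Jurkat numbers, the minimum of 35 T0 reads per construct, each line fitted alone, the tests of list differences in interaction scores, and the alternatives for the growth correlation and the slope through 0 were added only after the data were seen. Across alternatives, named growth effects kept direction and call in 719 cases, lost the call in 43 and reversed in 18, and named pair scores kept both in 888, lost the call in 78, gained one in 134, moved without a call in 99 and reversed in 11. List scores within a line kept their call in 81 cases, lost it in 61 and reversed in 14, and list differences in 82, 25 and 8. For pair scores, a line fitted alone and the fits without a replicate of the other line are the same fit, yet each is counted. Unless said otherwise, the cause was not tested. Power limits the pairs more than the genes. Of simulated pairs planted at −1 and 1, the shared fit recovered 14.7% and 39.4% in K562, and 14.7% and 30.3% in Jurkat, whereas every gene planted at −1 or 1 was recovered.

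Scaling decides the sign of weak growth effects by construction, since TMM and DESeq2's own size factors centre on the typical gene. With TMM 217 genes were lower and 195 higher in K562, 190 and 194 in Jurkat, and 217 and 164 in the difference. With DESeq2's own size factors these were 213 and 197, 179 and 218, and 201 and 177. Reversed under these 2 scalings were ZNF598 (1.94 and 1.94), C6orf203 in K562 (1.92 and 1.93), SFXN1 (1.90 and 1.91) and EMC1 (1.90 and 1.90). In Jurkat these were EFR3A (0.54 and 0.62), C6orf203 (0.52 and 0.60), SKIV2L2 (0.52 and 0.60), C11orf30 (0.51 and 0.59) and GPN3 (0.51 and 0.59). When every sgRNA had to pass, 258 genes were lower in Jurkat and 6 in the difference. A gene with 1 sgRNA faced no further sgRNA in this check. Jurkat effects scaled to K562 gave 154 lower and 216 higher. In the sgRNA readout, with K562 T0 from the barcode readout, 0 genes were higher in K562 (by edgeR, with 467 of 472 genes at an unadjusted p below 0.05 in either direction). Leaving out 1 library gave 0 to 1 genes higher in K562 and 0 to 1 in Jurkat, the 1 in Jurkat without Jurkat Endpoint replicate 1. The K562 count was 0 without either K562 T0 library, K562 Endpoint replicate 1 or either Jurkat T0 library. The lone sample is then assumed to vary like the other groups. The difference had 10 lower genes without Jurkat T0 replicate 2 (main 15).

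With the replicate number as a block, 465 genes were lower and 0 higher in K562 (edgeR, 465 at an unadjusted p below 0.05), and RPL35 lost its call (adjusted p = 0.0511), as did EFR3A (0.09) and C6orf203 (0.0677) in Jurkat. No other named growth call changed. The numbers do not show pairing, as deviations of T0 and endpoint samples with the same number correlated at 0.07 in K562 and −0.28 in Jurkat over 471 genes. With the Jurkat numbers crossed, the block gave 466 lower and 1 higher in K562, 397 and 0 in Jurkat, and 16 and 425 in the difference, and the interaction test 1584 negative and 2041 positive pairs in K562. With no replicate block, each endpoint set against both T0 libraries gave 1967 and 2618 pairs in K562 and 0 in Jurkat (limma, 3391 at an unadjusted p below 0.05).

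For interactions, the z-score gave 5262 negative and 4903 positive pairs in K562, 1999 and 2323 in Jurkat, and 3298 and 4177 in the difference. Its spread comes from pairs with non-targeting pseudo-genes, which may understate that of gene pairs and so make these counts too high. Each line fitted alone gave 603 and 722 in K562 and 161 and 171 in Jurkat, because the lines no longer share a spread. Leaving out 1 replicate gave 603 to 13160 negative and 722 to 14790 positive pairs in K562, 0 to 161 and 0 to 171 in Jurkat, and 0 to 7999 and 0 to 7227 in the difference, where by construction the lone replicate takes the spread of the other line. The lowest K562 counts are those of K562 fitted alone, the same K562 fit as with either Jurkat replicate left out. Likewise, with either K562 replicate left out, the Jurkat test is that of Jurkat alone. K562 had 8397 and 9362 without K562 replicate 1 and 13160 and 14790 without K562 replicate 2. In the same fits Jurkat had 161 and 171 without K562 replicate 1 or without K562 replicate 2, and the difference had 3623 and 3463 without K562 replicate 1 and 7999 and 7227 without K562 replicate 2. A pseudocount of 1 gave 1095 negative pairs in K562. Without a T0 minimum, 3549 pairs were positive in K562, 9 negative and 267 positive in Jurkat, and 67 and 17 in the difference. Scores scaled by the spread of non-targeting pairs gave 1058 positive pairs in K562, 44 and 37 in Jurkat, and 2 and 25 in the difference. Jurkat scores scaled to K562 gave 4 and 2 in the difference, and the authors' deposited phenotypes 4 and 3 in Jurkat. With 1 sgRNA order alone the K562 counts were 437 and 276 for AB, and 596 and 1000 for BA. With K562 T0 still from the barcode readout, tripleseq gave 3336 and 3775 in K562, and the sgRNA readout 4910 and 6093. These 2 settings moved the median growth effect of K562 by −0.20 and −0.20, and that of Jurkat by −0.07 and −0.05. For K562 they mix readouts and so do not test the readout alone. Of the 3956 K562 calls, 3316 stayed with the z-score, 1311 with K562 alone, 3376 in the tripleseq and 3346 in the sgRNA readout, and 442 and 884 in AB and BA order.

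The correlation of scores between lines (r = 0.147, rho = 0.135) was 0.132 with a pseudocount of 1 and 0.177 (rho 0.156) with 30. It was 0.242 (rho 0.219) without a T0 minimum, 0.168 with scores scaled by non-targeting spread, 0.177 (rho 0.173) for AB and 0.175 (rho 0.175) for BA, 0.187 (rho 0.161) in tripleseq and 0.182 (rho 0.162) in the sgRNA readout. Leaving out 1 replicate gave r of 0.105 to 0.127 and rho of 0.101 to 0.117. Jurkat lists passing numbered 5 to 9 and Jurkat profile lists 5 to 10 (main 19 and 12), with the lower lists value without Jurkat replicate 2 and the lower profile value without Jurkat replicate 1. With an estimated correlation, camera called 0 lists in each of the growth contrasts (adjusted p = 0.999), against 1, 1 and 3 with the preset correlation.

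With the additive expectation 2451 of the 3956 K562 calls stayed. It gave 310 negative and 98989 positive pairs in K562, 70 and 19256 in Jurkat, and 80080 and 415 in the difference, r of 0.428 and rho of 0.422. It also gave 65 and 39 passing list pairs in K562 and Jurkat, 4 and 2 profile lists, and 57 list differences. It reversed EIF3H with NUTF2 (0.34), RPL23 with RPL24 (0.22), NUBP1 with TAF2 (0.42), PELO with WDR61 (0.044), NCBP1 with NUDC (0.83), MRPL11 with PSMC1 (0.61), MAPKAP1 with MRPL27 (0.12), MAX with NDUFA8 (0.34), MCM4 with TIPIN (0.059), BNIP1 with COPA (1.85) and ASNA1 with SEC22B (0.20). Over the permuted mean, it reversed K562 means of mitochondrial ribosome and translation with the cytosolic ribosome (0.34), proteasome (0.23), DNA replication (0.37), translation initiation and elongation (0.34), Mediator and RNA polymerase II (0.25), mTORC1 (0.036) and mitosis (0.12), within ER-Golgi trafficking (0.20), and of RNA decay with mitochondrial import (−0.011) and nucleotide synthesis (−0.033). In Jurkat it reversed the mitochondrial ribosome within itself (−0.0025), with complex I (−0.0038) and with complexes III and IV and ATP synthase (−0.14), and ribosome biogenesis with mitosis (0.029). Reversed differences, again over the permuted mean, were those of the mitochondrial ribosome with the cytosolic ribosome (−0.29), proteasome (−0.22), DNA replication (−0.28), translation (−0.36), mTORC1 (−0.21) and mitosis (−0.18), of complexes III and IV and ATP synthase with mTORC1 (−0.13), and of nucleotide synthesis with RNA decay (0.27).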

Other observations

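The test of neighbouring genes was chosen only after the pair scores were seen, as were the gene pairs named for their profiles.

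Several gene pairs with the highest correlations of interaction profiles belong to shared complexes or steps, and others do not. In K562 the highest was MRPL43 with MRPS18A, both of the mitochondrial ribosome, at r = 0.739 (0.190 in Jurkat), and MRPL36 with MRPL37 stood at 0.675 in K562 and 0.579 in Jurkat. In Jurkat the highest was BDP1 of TFIIIB with SNAPC1 of the snRNA-activating complex, at 0.617 (0.258 in K562), and POLR3B, a subunit of RNA polymerase III, correlated with SNAPC1 at 0.485 (0.391 in K562). MED23 with MED24, both of Mediator, stood at 0.495 in Jurkat and 0.232 in K562, and LEO1 with WDR61, which also interacted negatively in both lines, at 0.483 and 0.626. The BNIP1 and RINT1 Jurkat profile correlation, between members of an ER tethering and fusion machinery, was 0.482, and 0.313 without Jurkat replicate 2. The 15 highest in Jurkat also held EIF4G2 with SNAPC1 (0.459) and POLN with TUBGCP5 (0.437), which share no gene list used here, and MINOS1 with MINOS1-NBL1 (0.497), a gene and its readthrough. Across alternatives, the highest profile correlations moved in 86 cases and stayed in 4. They are across genes, and the difference between lines was not tested. Over all 109746 gene pairs, profile correlations themselves agreed between the lines at r = 0.344 and rho = 0.294, where permuted gene labels reached at most 0.0346 (one-sided permutation p = 0.0001, the smallest they can give).

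Most pairs of neighbouring genes had negative scores. ERH with SLC39A9 and CENPK with PPWD1 were among the 8 lowest K562 pairs, and MRPL13 with MTBP and ATP5F1 with WDR77 among the 8 lowest of Jurkat fitted alone, and each is a pair of neighbours in the GRCh38 assembly. A candidate explanation is that an sgRNA acts at a shared or adjacent promoter, so that both sgRNAs repress the same gene. Some neighbours went the other way in both lines, namely MINOS1 with its readthrough MINOS1-NBL1 (0.044 in K562 and 0.22 in Jurkat) and DCTN4 with RBM22 (0.50 and 0.091). Without the 2 named from K562, the 17 remaining neighbouring pairs had a median score of −0.24 in K562, outside the 95% range of random pair sets (−0.15 to 0.16, two-sided permutation p = 0.0026), and −0.23 in Jurkat (p = 0.0002, the smallest they can give), with 14 and 15 below 0; without the extremes of both lines 15 pairs gave −0.23 (p = 0.0054) and −0.18 (p = 0.0002). Whether incomplete knockdown is deepened by another sgRNA at the same promoter stayed open, since constructs with 2 sgRNAs of the same gene scored below 0 for 57.9% of 387 genes in K562 (median −0.20) and 70.5% in Jurkat. No biological link between neighbours was tested.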
